A study of Mus musculus with 8 samples.

How the data were processed

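Gene expression was measured with 1 Affymetrix mouse expression array per animal in the hippocampus of the right hemisphere of 8 mice, 4 normal and 4 mutant. Per the labels, normal mice carried 1 mutant copy of Gusb (mps/+) and mutant mice carried 2 (mps/mps), on the B6.C-H2-Kbm1/ByBir background. Per the labels, normal and mutant mice were housed together, RNA was extracted with TRIzol and a lipid tissue kit, and 1 µg of RNA was copied to biotinylated RNA. Each array held a different animal, and both groups held 2 females and 2 males. The ages were 14.6 to 38.3 weeks in normal mice and 19.6 to 38.3 weeks in mutant mice.

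The deposited values are log2 expression values per probe set, background-corrected, normalized and summarised by the authors with RMA, and GCOS 1.4 is named per the submitters' processing notes. No scanner files were analysed here, so background correction and summarisation could not be repeated. The genome build behind the probe sets is not stated, and gene positions were used only to find which genes neighbour Gusb in the GRCm38.p6 gene table. The table held 22690 probe sets, of which 64 were controls. Of the others, 20380 carried 1 gene symbol, 691 carried several and 1555 listed no gene. The identifiers of 20351 of the probe sets with 1 symbol (99.9%) matched the gene table. Where a gene had more than 1 probe set (4956 genes), the probe set with the highest mean over all 8 arrays was used, which left 12393 genes. No dim gene was removed. Array medians lay between 6.09 and 6.17. Arrays give no counts, so the number of animals limits the precision. The 12 probe sets for bacterial transcripts absent from the samples had a median of 2.32 and a highest value of 3.62.

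Mutant and normal mice were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p 0.05. Changes are mutant minus normal on the log2 scale with the moderated standard error, and group values are means with SD. Gusb and the means of marker lists were also compared with a two-sided exact permutation test over the 70 arrangements of 8 arrays, whose smallest possible p is 0.0286. The 43 gene lists covered lysosome, matrix, glia, neurons, immune functions, stress, metabolism, hippocampal fields, neighbouring regions and other tissues. They were tested with limma camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. A list is named as higher or lower when it passed camera at the preset correlation. Members were counted past the threshold over all genes and adjusted over the list alone. Male and female mice were compared with genotype as a term, and the interaction of genotype and sex was tested across 4 cells of 2 animals. Genes within 10 Mb of Gusb were compared with other genes by a two-sided Fisher's exact test. RNA quality was read from the 3 prime minus 5 prime values of the actin and Gapdh control probe sets. Figures were drawn with Python 3.11.15.

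The lists, the tests, the threshold and the rule for named genes were chosen before the data were examined. The rule took Gusb, up to 12 genes per direction past the threshold with the largest change, the 4 members with the smallest p of each list past its threshold, 2 members of each other list, up to 3 genes per direction of the interaction, and the genes of the X and Y linked list. Genes named outside it are said to be chosen after their values were seen. The alternatives tried were the mean of all probe sets, leaving out probe sets whose names mark possible cross-hybridisation, leaving out the 40% of genes with the lowest mean, quantile normalization applied again, median centring, eBayes with trend and robust, array weights, sex, age, or both as covariates, animals of the same age as a random block, the lower or higher series of animal numbers as a block, and leaving out each animal in turn. After the data were examined, the first 1 or 2 principal components of the fixed regional marker lists were tried as covariates, and mutants 2 and 4 or normals 1 and 3 were left out. A fit with the replicate number as a block, the other Gusb probe set and a list of hypothalamic peptides were also added after the data were seen. The steps were tested on simulated data for mutant against normal mice over 12393 genes, where 68% of 100 genes changed by a log2 value of 1 and 95% of 100 genes changed by 2 were recovered. That run made 12 false calls, gave the right sign for 100% of the recovered genes and called 0 of 43 unchanged lists. The simulated genes varied independently of each other, unlike genes of 1 tissue or cell type. The 0 of 43 therefore does not show how often lists are falsely called in the real data. Probe sets with several symbols or no listed gene were tested apart and are not named.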

Results

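The series profiled hippocampal RNA from 4 normal and 4 mutant mice, 1 array per animal, to compare the mutant with the normal hippocampus. Mutant mice carry 2 copies of the mps allele of Gusb, which encodes the lysosomal enzyme beta-glucuronidase, and model mucopolysaccharidosis VII, a lysosomal storage disease. Pearson's r between arrays across probe sets lay between 0.951 (normals 1 and 4) and 0.994 (mutants 2 and 4), and probe sets are not independent replicates. The first 2 principal components held 35.5% and 23.7% of the variance. The number of animals, 4 per group, limits the precision of every value.

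All arrays are labelled hippocampus, but they differed in regional and other tissue markers within both groups. Differences between mutants and normals may thus include differences in tissue content. The mean of 11 thalamic and habenular genes ranged from 6.25 to 8.77 in normals and from 6.08 to 9.13 in mutants, with mutants 2 and 4 and normal 2 highest. The mean of 5 CA1 pyramidal genes was 8.88 in mutant 3 and 6.54 to 6.79 in the other mutants, against 6.81 to 8.44 in normals. Striatal genes had a mean of 8.90 to 10.1 in normals 1, 3 and 4, and of 6.33 to 7.18 in the other 5 arrays. Choroid plexus genes had a mean of 7.75 in mutant 1 and 6.77 in mutant 3, against 4.49 to 5.37 in the other 6. RNA of normal 1 differed in quality, with a mean 3 prime minus 5 prime value of 3.58 against 0.22 to 0.75 in the other 7 arrays. Normal 4, at 14.6 weeks, was the youngest animal, and no mutant was younger than 19.6 weeks.

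**Figure D1:**
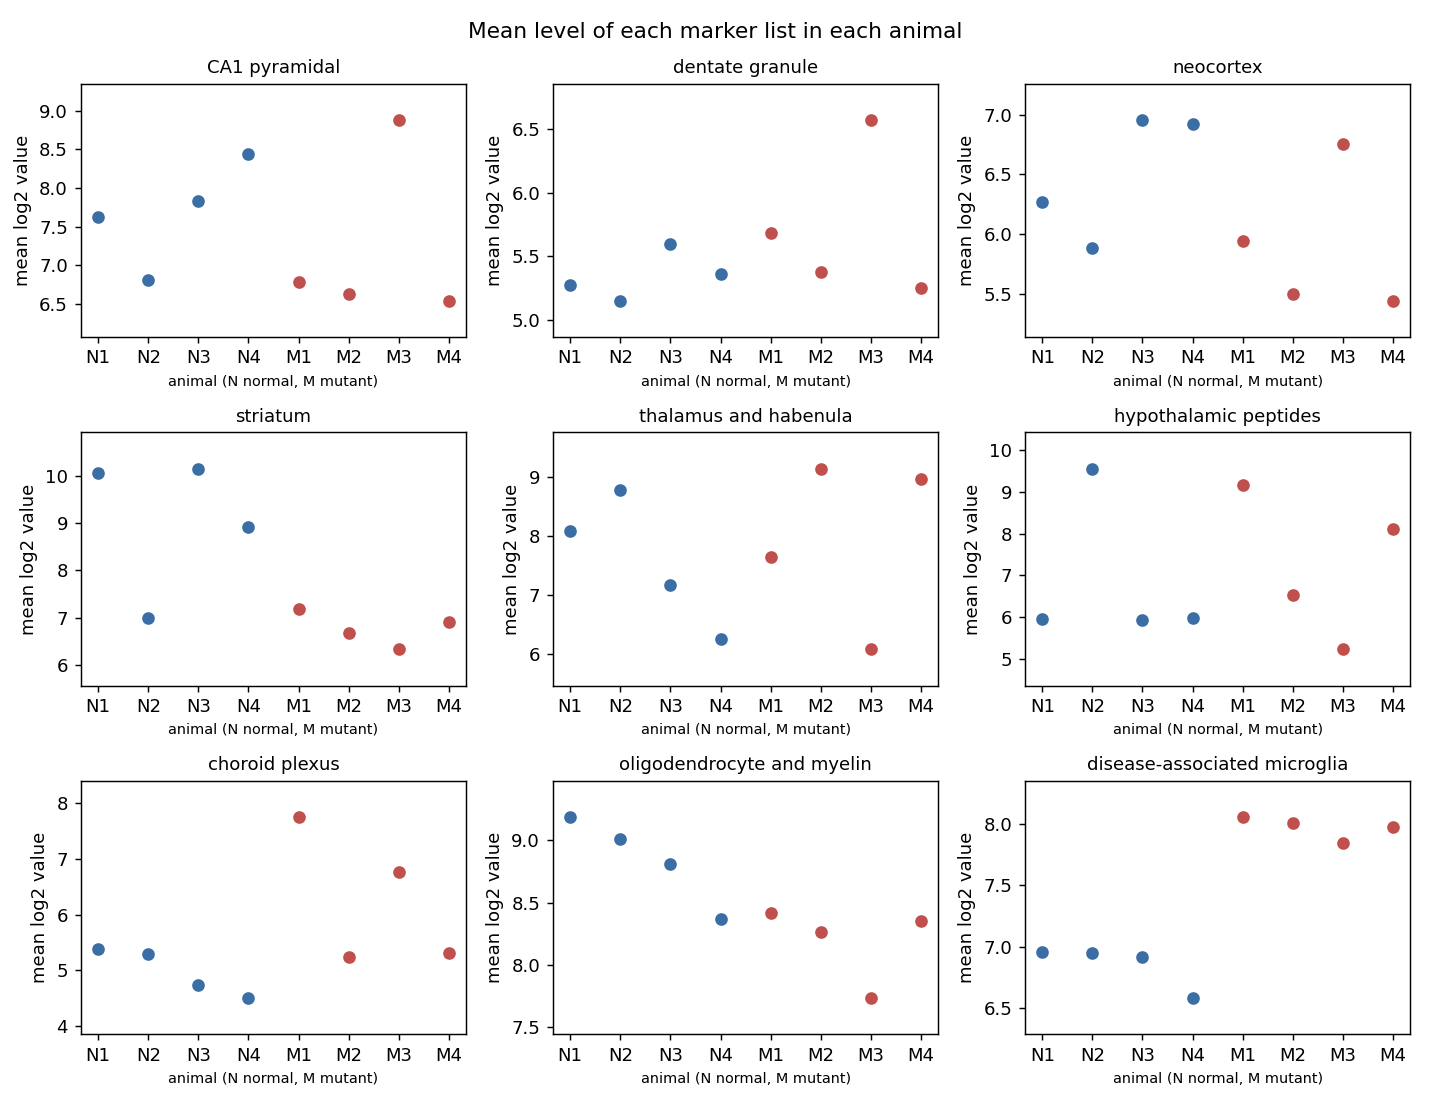
Mean log2 expression of marker gene lists (vertical axis) in each array, with normal and mutant animals as separate points. Thalamic means ranged from 6.25 to 8.77 in normals and from 6.08 to 9.13 in mutants, and the 2 highest choroid plexus means were 7.75 in mutant 1 and 6.77 in mutant 3.

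Gusb was measured by 2 probe sets that differed. The probe set with the lower overall mean had a mean of 5.95 ± 0.48 (SD, n = 4) in normals and 4.55 ± 0.15 (SD, n = 4) in mutants, 2.64-fold lower. Its highest mutant value, 4.71, lay below its lowest normal value, 5.40 (two-sided exact permutation p = 0.0286, the smallest the design can give). Over all probe sets this log2 change of -1.40 ± 0.23 (SE) did not pass in limma (adjusted p = 0.136). The other probe set, used for the gene because its overall mean was higher, had means of 5.77 ± 0.53 and 5.93 ± 0.48 (SD, n = 4 each, two-sided exact permutation p = 0.657). Its change of 0.16 turned to -0.057 without normal 1 and to -0.061 without mutant 1.

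Genes of activated microglia and macrophages and the astrocyte filament gene Gfap were higher in the mutant arrays, whose tissue is labelled hippocampus. Of 12393 genes, 12 rose and 1 fell past adjusted p 0.05 in limma. All 4 mutants lay beyond all 4 normals for each of the 13, which their selection on the same values makes likely. Among genes past the threshold and above the absent bacterial controls in both groups, the largest increases were in Clec7a, a receptor for beta-glucan (log2 3.38 ± 0.26 SE, 10.4-fold, adjusted p = 0.00181), and Gpnmb, a transmembrane glycoprotein of phagocytes (3.30 ± 0.18, 9.83-fold, adjusted p = 0.000370). Cst7, the gene of the cysteine protease inhibitor cystatin F, was at 3.23 ± 0.06 in normals, within the range of absent controls (up to 3.62), and at 6.47 ± 0.40 in mutants (SD, n = 4 each). Its mutant mean was 7.21-fold above the highest absent control (limma adjusted p = 0.000370). The lysozyme gene Lyz2 rose 7.49-fold. Lyz1 rose 7.35-fold on a probe set named for possible cross-hybridisation, and by a log2 value of 2.75 on another so named (adjusted p = 0.0412 over all probe sets). Its remaining probe set (0.17) did not exceed the absent controls in any array. Gfap went from 7.52 ± 0.33 to 9.79 ± 0.35 (SD, n = 4 each), a 4.82-fold rise. The phagocyte genes Cd68 (4.24-fold), Mpeg1, which encodes a pore-forming protein (4.19-fold), and Ms4a7 (3.69-fold) also rose. Smaller increases were seen in Cd84 (2.56-fold), the complement C3a receptor gene C3ar1 (2.52-fold) and Adgre1, a macrophage marker gene (2.23-fold). Lpar1, which encodes a lysophosphatidic acid receptor, fell by 1.11 on the log2 scale (adjusted p = 0.0111), from 8.32 ± 0.13 to 7.20 ± 0.14 (SD, n = 4 each). Its other 2 probe sets changed by -0.74 and -1.01 without passing. At an unadjusted p under 0.05, 809 genes passed where 619.7 would by chance, 502 higher and 307 lower in mutants. The groups did not overlap for 481 genes, where chance gives 2.86%, or 354. Leaving out 1 animal gave 12, 18, 7 and 8 increases without normals 1 to 4 and 6, 6, 11 and 5 without mutants 1 to 4. The count of decreases was 22 without normal 2 and 0 without normals 3 or 4 or mutants 2 or 4.

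Clec7a, Gpnmb, Cst7, Mpeg1 and Cd84 passed in each of the 8 fits that left out 1 animal. Gfap passed in 7, Lyz2 in 5 and Lpar1 in 4 of these fits, and Cd68, Lyz1, Ms4a7, C3ar1 and Adgre1 in 2. With the first 2 regional components as covariates, 5 genes rose and 0 fell, Clec7a, Gpnmb, Cst7, Cd68 and Mpeg1 among the former. The second component was higher in each mutant (0.84 to 7.57) than in each normal (-7.02 to 0.62). This fit can thus also take out part of a genotype difference.

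**Figure D2:**
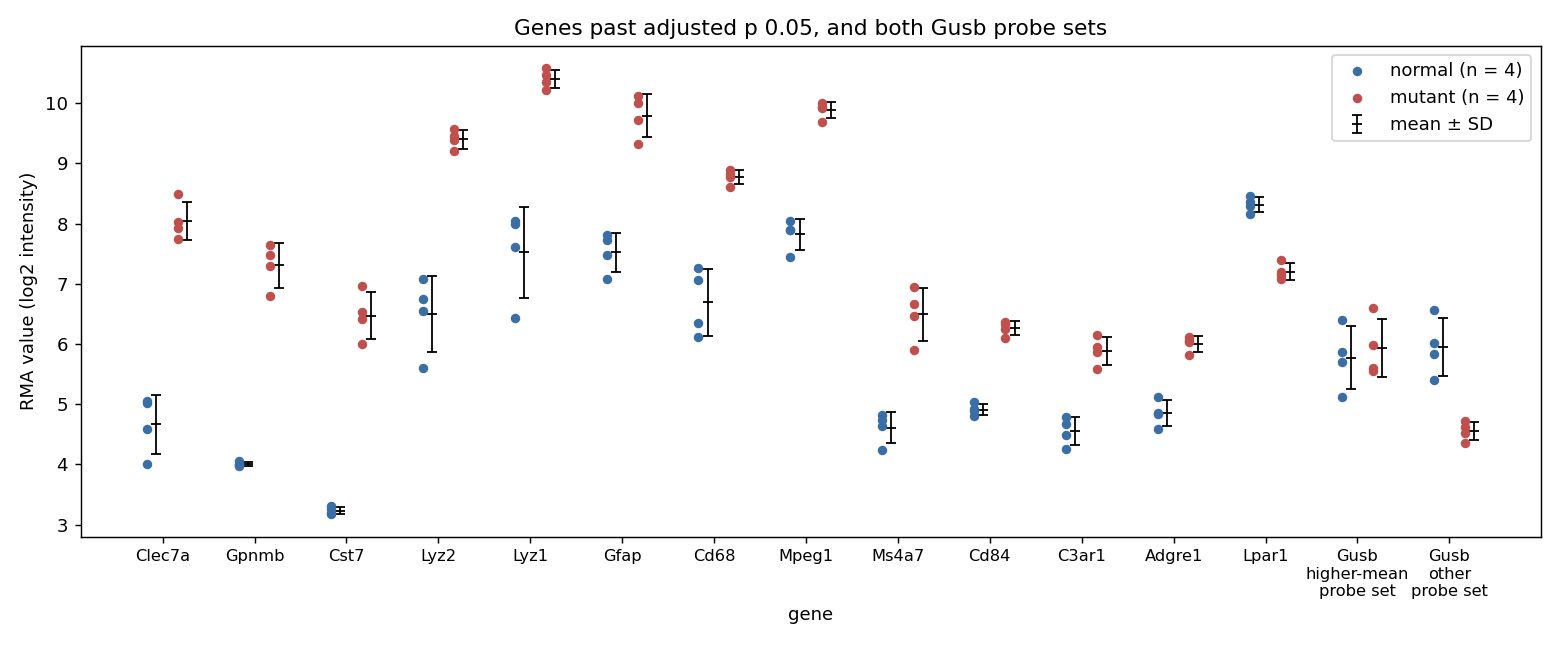
Log2 expression (vertical axis) of the 13 genes past adjusted p 0.05 in each normal and mutant animal, with group means and SD. For Gpnmb the normals sit at 4.01 ± 0.04 and the mutants at 7.31 ± 0.37, and Lpar1 is lower in mutants.

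Microglial gene lists were higher in mutants. Of 29 measured disease-associated microglia genes, 26 had higher means and 5 rose over all genes, while 22 rose adjusted over the list alone (median log2 change 0.91, camera adjusted p = 1.26e-27). This call held with an estimated correlation (adjusted p = 0.0120). The list mean was 7.85 to 8.06 in mutants and 6.58 to 6.95 in normals (two-sided exact permutation p = 0.0286, the smallest possible), and normal 4 lay lowest. The list shares 13 of its members with other lists. Of 30 general microglia and macrophage genes, 26 had higher means, with 2 past over all genes and 12 up and 1 down adjusted over the list alone (median 0.49, camera adjusted p = 7.72e-13, adjusted p = 0.0800 with an estimated correlation). Besides Mpeg1 and Cd84, these included Trem2, a microglial lipid receptor gene (1.52, list adjusted p = 0.00255), and Ctss, which encodes cathepsin S (0.90). Trem2 was at -0.11 when probe sets named for possible cross-hybridisation were left out, on a probe set whose values lay between 3.73 and 4.05. Of 13 homeostatic microglia genes the list did not pass (median -0.08, camera adjusted p = 0.313), with 0 genes past over all genes, and Fcrls up (0.89) and Selplg down (-0.91) adjusted over the list alone. Without mutant 3, whose mean of 7.66 stood above 7.15 to 7.18 in the other mutants, its median was -0.18 and the list passed, as it did without dim genes (-0.21). Fry's mixed test, which asks for change in either direction, passed for it (adjusted p = 3.79e-05).

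Lysosomal genes were higher in mutants by small amounts. Of 30 hydrolases and activators, 29 had higher means, 0 passed over all genes and 3 rose adjusted over the list alone (median 0.27, camera adjusted p = 4.58e-09, adjusted p = 0.0535 with an estimated correlation). These were Man2b1, a lysosomal alpha-mannosidase gene (0.56), Galns, a sulfatase gene for keratan and chondroitin sulfate (0.74), and Naglu, a heparan sulfate hydrolase gene (0.77), while the fucosidase gene Fuca1 was at 0.50. The mutated gene Gusb is itself among the 29, at 0.16 on the probe set used for the gene. Its other probe set was 2.64-fold lower in mutants. Of 14 cathepsins and cystatins, 13 had higher means, 1 passed over all genes and 9 rose adjusted over the list alone (median 0.50, camera adjusted p = 8.34e-13). This call held with an estimated correlation (adjusted p = 0.0335). Of the 14, 5 (Ctsb, Ctsd, Ctss, Ctsz and Cst7) are also in the microglia lists, so this rise is not independent of theirs. Besides Cst7, the members with the smallest p were the cathepsin genes Ctsz (0.91), Ctss (0.90) and Ctsl (0.51). Of 27 lysosomal membrane and acidification genes, 24 had higher means, 1 passed over all genes and 2 rose adjusted over the list alone (median 0.13, camera adjusted p = 4.94e-05). It held with an estimated correlation (adjusted p = 0.0404), and 2 of its genes, Cd68 and Laptm5, are also in the microglia lists. Besides Cd68, these were led by the cholesterol transfer gene Npc2 (0.68), with Lamp2 (0.70) and Laptm5 (0.91) not past. In all 3 lists each mutant mean lay above each normal mean, with hydrolase means of 7.79 to 8.01 against 7.53 to 7.72. The autophagy list did not pass (median -0.05, mean 0.01, camera adjusted p = 0.538), with Ulk1 at 0.28 and Atg7 at 0.34.

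Lists for the stored material did not pass. The glycosaminoglycan synthesis list had a median of -0.03 (camera adjusted p = 0.343), with Chst15 at -1.30 and Chst11 within the range of absent controls in both groups (means of 3.19 and 2.85). Proteoglycans and brain matrix had a median of 0.14 (adjusted p = 0.162), with Cd44 at 0.94 and Sdc4 at 0.46. Ganglioside metabolism had a median of 0.08 (adjusted p = 0.162), with Neu1 at 0.34 and Gm2a at 0.59. In each of these 3 lists 0 genes passed over all genes or adjusted over the list alone.

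The complement, MHC class I, interferon and cytokine lists were higher in mutants, while the MHC class II and lymphocyte lists did not pass. Of 15 complement genes, 12 had higher means, 1 passed over all genes and 5 rose adjusted over the list alone (median 0.31, camera adjusted p = 8.38e-06, adjusted p = 0.145 with an estimated correlation). Besides C3ar1 these included C1qc (1.46) and C1qb (1.32), which encode chains of the first complement component, and C2 (0.95). C1qa, C1qb and C1qc are also in the general microglia list and Serping1 in the reactive astrocyte list. B2m of the MHC class I list and Ccl3, Ccl4, Ccl6 and Csf1 of the cytokine list are also disease-associated microglia genes. These rises are thus not independent of the glial ones. The complement median ran from 0.22 to 1.39 over the 25 alternatives. All 12 MHC class I and antigen processing genes had higher means, with 0 past over all genes and 8 up adjusted over the list alone (median 0.60, camera adjusted p = 1.38e-11, adjusted p = 0.147 with an estimated correlation). H2-K1 (0.86), B2m (0.98), Tapbp (0.52) and H2-D1 (0.86) had the smallest p, and H2-D1 was at 0.45 without probe sets named for possible cross-hybridisation and at 0.29 with the mean of its probe sets. The interferon list had 20 of 24 means higher and 0 genes past over all genes or adjusted over the list alone (median 0.18, camera adjusted p = 0.00218, adjusted p = 0.418 with an estimated correlation). Its members with the smallest p were Ifit3 (0.69), Bst2 (0.80), Ifit2 (0.77) and Ifi35 (0.40), and without normal 4 the median was 0.085 and the call ended. The interferon median ran from 0.085 to 0.69 over the 25 alternatives. Cytokines and chemokines had 21 of 28 means higher, with 0 past over all genes and 5 up and 2 down adjusted over the list alone (median 0.087, camera adjusted p = 0.0253, adjusted p = 0.420 with an estimated correlation). Ccl3 (from 3.07, within the range of absent controls, to 4.96), Tgfb1 (0.73) and Tgfb2 (1.26) were up and Il33 was down (-0.77). Its call ended without normal 1 (0.095), normal 4 (0.026), mutant 1 (0.084) or mutant 2 (0.084). Counting all 25 alternatives it ended in 13, and the median ran from 0.026 to 0.24. MHC class II did not pass (median -0.03, camera adjusted p = 0.479), with H2-DMa at -0.32 and H2-Ab1 at -0.16 (0.11 without probe sets named for possible cross-hybridisation), nor did lymphocyte genes (median -0.05, adjusted p = 0.293), with Ighm at -1.09 and Jchain near the absent controls (means of 3.26 and 3.69). Both had 0 members past over all genes or adjusted over the list alone.

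Astrocyte genes were higher in mutants. Of 28 reactive astrocyte genes, 24 had higher means, 1 (Gfap) passed over all genes and 7 rose adjusted over the list alone (median 0.33, camera adjusted p = 2.45e-08, adjusted p = 0.145 with an estimated correlation). Serpina3n, a protease inhibitor gene (1.89), the cytokine receptor gene Osmr (1.20) and the filament gene Vim (0.93) were among them. Of 22 general astrocyte genes, 18 had higher means and 0 passed over all genes or adjusted over the list alone (median 0.23, camera adjusted p = 0.000399, adjusted p = 0.161 with an estimated correlation). Its smallest p were for the water channel gene Aqp4 (0.76), Sox9 (0.58), Clu (0.25) and Atp1b2 (0.60).

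Oligodendrocyte and myelin genes were lower in mutants. Of 28 genes, 27 had lower means, 0 passed over all genes and 11 fell adjusted over the list alone (median -0.68, camera adjusted p = 1.34e-17, adjusted p = 0.145 with an estimated correlation). They included Car2, which encodes carbonic anhydrase II (-0.80), Adamts4, a protease gene (-0.81), Evi2a (-0.89) and the myelin enzyme gene Cnp (-0.84). The list mean was 7.73 to 8.42 in mutants and 8.37 to 9.18 in normals (two-sided exact permutation p = 0.0571). Normal 1, whose 3 prime minus 5 prime value was 3.58, had the highest mean, and mutant 3, with the highest CA1 mean, the lowest. Oligodendrocyte precursor genes did not pass (median -0.13, camera adjusted p = 0.490), with C1ql1 at 0.38, Ptprz1 at 0.40 and 0 members past over all genes or adjusted over the list alone.

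Choroid plexus and meningeal genes were higher in mutants, chiefly in mutants 1 and 3. All 15 choroid plexus genes had higher means, with 0 past over all genes or adjusted over the list alone (median 1.30, camera adjusted p = 2.45e-08, adjusted p = 0.266 with an estimated correlation). The list means were 7.75 and 6.77 in mutants 1 and 3, and 5.24 and 5.31 in mutants 2 and 4, against 4.49 to 5.37 in normals. Col8a1 (0.54), Otx2 (1.30), Cldn2 (1.55) and Wfdc2 (0.93) had the smallest p. Of 19 meningeal and fibroblast genes, 18 had higher means, 0 passed over all genes and 5 rose adjusted over the list alone (median 0.64, camera adjusted p = 1.24e-08, adjusted p = 0.213 with an estimated correlation). They included Aebp1 (0.83), the matrix genes Lum (1.33) and Dcn (1.42), and Slc6a13 (0.82), and the means were 6.81 and 7.21 in mutants 1 and 3 against 5.60 to 6.46 elsewhere. Of 20 endothelial genes, 19 had higher means and 0 passed over all genes or adjusted over the list alone (median 0.23, camera adjusted p = 0.000508, adjusted p = 0.266 with an estimated correlation), with Vwf at 1.05, Kdr at 0.37, Egfl7 at 0.36 and Ramp2 at 0.64. Normal 4 had the lowest endothelial mean, 6.84, and the call ended with the first 2 regional components as covariates (0.31). Pericyte and smooth muscle genes (median 0.16, camera adjusted p = 0.104), with Notch3 at 0.49 and Pdgfrb at 0.42, did not pass except without normal 3 (0.19) or without normals 1 and 3 (0.24). Red cell and neutrophil genes did not pass (median 0.0016, mean -0.04, adjusted p = 0.679), with Bpgm at -0.18 and Hbb-b2 near the absent controls (means of 3.41 and 3.65). The last 2 lists had 0 members past over all genes or adjusted over the list alone.

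The striatal and inhibitory neuron lists passed as lower in mutants. The striatal genes were high in only 3 normals, and the inhibitory neuron genes changed in both directions. All 6 striatal genes had lower means, with 0 past over all genes and 5 down adjusted over the list alone (median -2.32, camera adjusted p = 2.37e-08, adjusted p = 0.145 with an estimated correlation). Penk, an opioid peptide gene (-3.34), Rgs9 (-2.37), Pde10a (-1.31) and the dopamine receptor gene Drd2 (-2.27) had the smallest p. The striatal mean of normal 2 lay within the range of the mutants (6.33 to 7.18). Striatal tissue in the dissections of the other normals was not tested apart from these genes and stays open. Without normal 2, Penk (-4.13), Rgs9 (-3.03) and Pde10a (-1.71) passed over all genes. Of 20 inhibitory neuron genes, 15 had lower means, 0 passed over all genes and 1, the transcription factor gene Dlx5 (-1.49), fell adjusted over the list alone (median -0.49, camera adjusted p = 0.000807, adjusted p = 0.145 with an estimated correlation). The GABA transporter gene Slc32a1 was at -1.01, Tac1 at -1.56 and Gad1 at -0.52, and without mutants 2 and 4 the list median was -0.045 and the call ended. Members with higher means, named after their values were seen, were Calb2 (1.11), Sncg (0.91), Cck (0.65), Pvalb (0.53) and Htr3a (0.18), and Sst was at -0.12. The list thus did not fall as a whole, and a link of its fall to the striatal genes was not tested. Of 21 excitatory synapse genes, 14 had lower means and 0 passed over all genes or adjusted over the list alone (median -0.17, camera adjusted p = 0.0496, adjusted p = 0.562 with an estimated correlation), with Gria4 at -0.71, Homer1 at -1.49, Vamp2 at 0.40 (-0.11 with the mean of its probe sets) and Grin2b at -0.49. Among the fits leaving out 1 animal, the call held without normal 1 or mutant 3 and ended without normals 2 (-0.21), 3 (-0.084) or 4 (-0.15) or mutants 1 (-0.074), 2 (-0.21) or 4 (-0.16). The excitatory call held in only 9 of the 25 alternatives. It ended in 15, among them the mean of all probe sets (-0.12), and the sign turned in 1. Of 15 neurogenesis and proliferation genes, 12 had lower means and 0 passed over all genes or adjusted over the list alone (median -0.16, camera adjusted p = 0.0119, adjusted p = 0.237 with an estimated correlation). The proliferation genes Top2a, Cdk1 (-0.56) and Mki67 and Igfbpl1 (-0.44) had the smallest p. Top2a and Mki67 had means of 4.04 and 3.75 in normals and of 3.14 and 3.25 in mutants, within the range of absent controls, so the size of their change is not known. Without normal 4, the youngest animal (14.6 weeks), the list median was -0.058 and the call ended. It ended in 4 of the 25 alternatives in all, and the sign turned in 1 more.

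Apart from striatum, the lists of hippocampal fields, thalamus and neocortex did not pass in the planned comparison before any alternative, and 0 of their members passed over all genes or adjusted over the list alone. Medians were -0.50 for CA1 (camera adjusted p = 0.259), with Pou3f1 at -1.34 and Lefty1 at 0.36, and 0.20 for CA2 and CA3 (mean -0.04, adjusted p = 0.538), with Coch at -1.43 and Bok at 0.52. Dentate granule genes had a median of 0.14 (adjusted p = 0.347), with Dsp at 1.27 and Prox1 at 3.24 in normals, within the range of absent controls, and 4.16 in mutants. The thalamic list had a median of 0.42 (adjusted p = 0.484), with Rorb at -0.38 and Slc17a6 at 0.79, and neocortical genes -0.35 (adjusted p = 0.0697), with Foxp2 at -1.13 and Lamp5 at -1.92. Without mutant 3, the CA1 (-1.03), thalamic (1.05) and neocortical (-0.49) lists passed, and neocortex also without normal 1 (-0.53). Over the 25 alternatives, CA1 passed in 3, thalamus in 3 (in 2 of them lower in mutants), neocortex in 8 and dentate in 2, among them CA1 (-0.55) and neocortex (-1.15) without dim genes. Dentate passed with the first regional component (0.55) and without mutants 2 and 4 (0.28). The regional components are built from the genes of these lists, and mutants 2 and 4 were left out for their regional marker values, so passing in these fits is no independent evidence. General neuron genes did not pass (median 0.17, adjusted p = 0.281), with Syp at 0.72 and Stmn2 at 0.32. Immediate early genes had a median of -0.21 (adjusted p = 0.0732), with Egr2 at -2.52 and Egr1 at -1.31, and passed in 5 of the alternatives, including those without normal 2 (-0.21) or mutant 3 (-0.28).

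Metabolic lists were higher in mutants, with normal 4 low in 3 of the 4. Of 19 cholesterol synthesis genes, 18 had higher means and 0 passed over all genes or adjusted over the list alone (median 0.31, camera adjusted p = 6.17e-07, adjusted p = 0.145 with an estimated correlation), with Tm7sf2 at 0.52, Mvd at 0.43, Lss at 0.60 and Sqle at 0.48. Each mutant mean for this list (8.31 to 8.58) lay above each normal mean (8.03 to 8.29), and the call ended with the first 2 regional components as covariates (0.13). Ribosomal protein genes had 27 of 28 means higher and 0 past over all genes or adjusted over the list alone (median 0.29, camera adjusted p = 0.00141, adjusted p = 0.562 with an estimated correlation), with Rpl8 at 0.31, Rpl7 at 0.18, Rpl19 at 0.29 and Rps4x at 0.19 (-0.0060 with the mean of its probe sets). Oxidative phosphorylation genes had 35 of 41 means higher and 0 past over all genes or adjusted over the list alone (median 0.24, camera adjusted p = 0.0134, adjusted p = 0.614 with an estimated correlation), with Sdhd at -0.17, Cox8a at 0.53, Cox4i1 at 0.34 and Ndufb2 at 0.55. Normal 4 had a ribosomal mean of 9.90 and an oxidative phosphorylation mean of 9.99, against 10.8 to 11.2 and 10.96 to 11.2 in the other 7 arrays. Without normal 4 the medians were 0.0080 and -0.039 and both calls ended, as they did without mutant 1 (0.22 and 0.24). Of the 25 alternatives, the ribosomal call ended in 4. The oxidative phosphorylation call ended with its sign kept in 6 and with its sign turned in 1. Of 17 oxidative stress and metal handling genes, 11 had higher means, 0 passed over all genes and 2, Hmox1 (0.47) and Slc7a11 (0.56), rose adjusted over the list alone (median 0.41, camera adjusted p = 0.0336, adjusted p = 0.482 with an estimated correlation). Cat was at 0.41 and Nqo1 at 0.41, and the call ended without normal 4 (0.067), mutant 1 (0.33) or mutant 4 (0.38). In all it ended in 13 of the 25 alternatives, among them the mean of all probe sets (0.22), and the median ran from 0.033 to 0.41. Heat shock genes (median -0.15, adjusted p = 0.121), with Hsph1 at -0.39 and Bag3 at 0.36, passed only without normal 3 (-0.21) among the fits leaving out 1 animal. Genes of the endoplasmic reticulum stress response did not pass (median 0.0063, adjusted p = 0.861), with Atf3 at 0.38 and Chac1 at 0.31. These last 2 lists had 0 members past over all genes or adjusted over the list alone.

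Across the 43 lists, 23 passed camera at the preset correlation, 18 higher and 5 lower in mutants. With an estimated correlation 3 held, those of disease-associated microglia, cathepsins and lysosomal membrane, and 6 passed fry. The count was 16 without normal 4 and 28 without mutant 3. Splits of the same arrays that mixed the genotypes gave 1 to 24 lists at the preset correlation. A call at that setting alone therefore does not set genotype apart from other differences between the arrays.

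**Figure D3:**
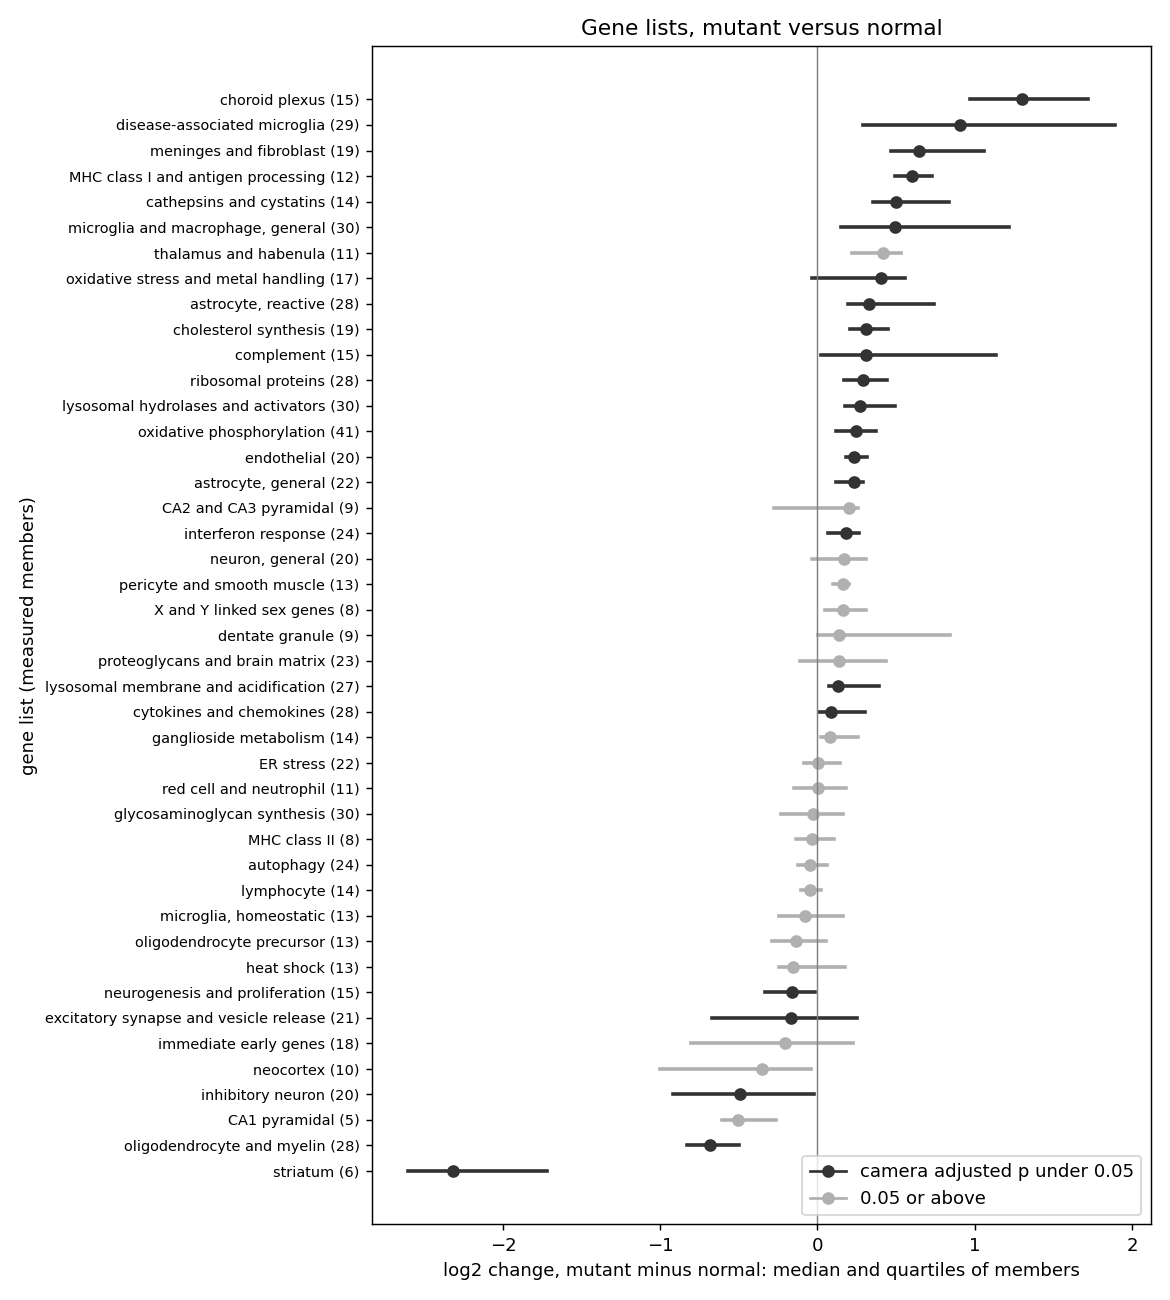
Median log2 change, mutant minus normal (horizontal axis), of the 43 fixed gene lists, with the quartiles of the members. The medians run from -2.32 for striatum to 1.30 for choroid plexus, and 23 lists passed camera adjusted p 0.05.

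Male and female mice differed in 4 genes, all of the X and Y linked list. The Y-linked genes Eif2s3y, Kdm5d and Uty had means of 7.40, 5.67 and 5.13 in males and of 2.02, 2.28 and 3.23 in females, within the range of absent controls, so the size of their difference is not known. Xist, the X inactivation transcript, was lower in males (-5.69, limma adjusted p = 0.00130). The values matched the sex labels of all 8 animals. Of the other members, Kdm5c was at -0.09, Kdm6a at -0.81, Eif2s3x at -0.64 and Ddx3x at -0.37 without passing. Among mutant against normal differences this list did not pass (median 0.16, camera adjusted p = 0.492). For the difference between the genotype change in males and that in females, 0 genes passed in limma, and 1419 had an unadjusted p under 0.05 where 619.7 would by chance (lowest adjusted p 0.340), more than the 809 of the genotype comparison. The smallest p were for Rp2 (1.71), Sox11 (1.61) and Sirt1 (1.65), whose mutant minus normal change was higher in males, and for Urm1 (-1.64), Cuta (-2.21) and Rhog (-1.65), whose change was lower. Without normal 3, 1 gene passed. The normal females were normals 1 and 4, which had the lowest weights (0.391 and 0.475) in the fit with array weights. Normal 1 also differed in RNA quality, so traits of these 2 arrays cannot be told apart from an interaction.

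No gathering of changed genes around Gusb on chromosome 5 was found. Of 203 genes within 10 Mb, 0 passed in limma, against 13 of 12173 elsewhere (two-sided Fisher's exact p = 1). With so few genes called, 0 near Gusb is likely by chance, so this count cannot exclude a gathering. At an unadjusted p under 0.05 the shares were 7.39% and 6.51% (two-sided Fisher's exact p = 0.567). Within 5 Mb they were 10.3% (4 of 39 genes) and 6.52% (two-sided Fisher's exact p = 0.320). The group difference in the mean 3 prime minus 5 prime value was within the spread of the animals (mutant minus normal -0.55, two-sided exact permutation p = 0.971), and without normal 1 the difference was 0.28 (exact p = 0.0857).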

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

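The tests of the regional, myelin and choroid plexus patterns were chosen after the results were seen, while the counts over other splits of the arrays were planned before. The bounds of both myelin tests were set after their values were seen. The bound for regional content was then changed to match the one for RNA quality, which turned that result from undecided to against. A test of RNA quality for the thalamic pattern was dropped for one of exchanged labels. A count of choroid plexus and meningeal genes highest in mutants 1 and 3 was dropped because those arrays had been picked on the same values.

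Chance could not be excluded for the counts of genes and lists. Of the 35 splits of the 8 arrays, the real one included, 2 gave at least as many genes as the real 13 and 2 at least as many lists as the real 23. The highest other counts were 236 genes and 24 lists, both in the same split. Of the remaining splits, the one by sex gave 3 genes and 7 lists. The others gave 0 genes, while all of them called lists, from 1 to 21. The split with 236 genes set normals 1, 3 and 4 and mutant 3 against normal 2 and mutants 1, 2 and 4, which points to a structure of the samples. With the first regional component as a covariate genotype gave 11 increases and 1 decrease, and with the first 2 it gave 5 and 0. The second component itself separated normals from mutants. For sex, 3 of 34 splits, the real one included, gave at least as many genes as the real 4, with a highest other count of 74 in the split that gave 236 for genotype.

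Thalamic and habenular markers differed between arrays by up to 3.05 on the log2 scale. Genotype as the cause was argued against, since the group difference of 0.38 was smaller than the ranges within groups, 2.52 and 3.05, and age or sex as the whole cause, since mutants 2 and 3, both males of 25.6 weeks, had the highest and the lowest mean and differed by 3.05. An exchange of the labels of normal 2 and mutant 3 was also argued against, because the disease-associated microglia mean of mutant 3 lay 0.89 above the highest normal and that of normal 2 lay 0.90 below the lowest mutant. The thalamic mean fell where the mean of the neocortical and CA1 lists rose (Pearson r = -0.936, exact permutation p = 0.00154, Spearman's rho = -0.952, exact permutation p = 0.00114, n = 8, 1 relation computed), with r = -0.8286 (exact permutation p = 0.0375) without mutant 3 and normal 4 and 1 gene, Rorb, in both the thalamic and the neocortical list. Regional content of the dissected tissue is a candidate explanation, found and tested on the same data, while the 2 series of animal numbers, with 4 arrays each (r = -0.552 and -0.986, too few to test), stay open.

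Myelin genes were lower in mutants (median -0.68). RNA quality of normal 1 as the whole cause was argued against by a median of -0.56 without that animal. With the first 2 regional components the median was -0.55, and the list passed camera at the preset correlation in both fits. Under the changed bound this counted against regional neuronal content as the whole cause, but under the earlier bound it was undecided. No conclusion on regional content is drawn from it. The second of these components separated normals from mutants, so the fit with components cannot fully part regional content from genotype. The share of white matter in each dissection was not measured apart from these genes, so it cannot be separated from a genotype effect here. Genotype, regional neuronal content, white matter content and age may each contribute, and the list's call did not hold with an estimated correlation (adjusted p = 0.145).

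Choroid plexus and meningeal genes were higher in mutants 1 and 3. None of the 15 choroid plexus and 19 meningeal genes is in another list, and 12 and 17 of them exceeded every absent control in all normals. Ttr, the choroid plexus gene with the highest signal, was at 13.9 and 13.7 in mutants 1 and 3 and 8.22 to 12.1 elsewhere. For the choroid plexus list mean, a rise in every mutant by genotype was argued against, since the higher of mutants 2 and 4, 5.31, lay below the highest normal, 5.37. In Otx2, Col8a1, Wfdc2 and Sostdc1, picked after their values were seen, each mutant lay above each normal by a small margin (Otx2 6.37 against 6.33). The groups overlapped in the other choroid plexus genes. Choroid plexus and meningeal tissue in these dissections was not tested apart from the genes of these 2 lists and stays open, as does genotype for single choroid plexus genes and for the meningeal genes.

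Samples far from the others of their group were looked for in 372 groups of 4, where 24 were found and 18.6 are given by chance (1 in 20); the values below are the gap to the nearest other animal as a share of the group's range. The quality measures of normal 1 stood apart for actin (0.921, level 2.26 against 0.81 to 0.92) and Gapdh (0.973, level 4.90 against -0.36 to -0.22). Mutant 3 stood apart in the means of homeostatic microglia (0.953), excitatory synapse (0.925) and CA1 genes (0.896), and mutant 1 in general neuron genes (0.858). Normal 4 stood apart in the means of disease-associated microglia (0.895) and pericyte genes (0.942). Among genes, mutant 3 was highest for Tgfb2 (0.879) and Pou3f1 (0.915) and lowest for Gria4 (0.953) and Bpgm (0.887). Mutant 1 was highest for Neu1 (0.930), H2-Ab1 (0.853) and Igfbpl1 (0.8294) and lowest for Vwf (0.899), and mutant 2 was lowest for Bag3 (0.931). Normal 3 was highest for Man2b1 (0.852) and Cnp (0.959) and lowest for Adamts4 (0.905). Normal 2 was lowest for Chst15 (0.981) and highest for Notch3 (0.963), normal 1 was highest for Car2 (0.897), and normal 4 was lowest for Ctss (0.845). Outside the genes compared, 2 of 2246 probe sets with several symbols or no listed gene passed adjusted p 0.05 (log2 changes of 2.54 and 2.27).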

How the results depend on the processing

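The regional covariates, the fits without mutants 2 and 4 or without normals 1 and 3, the replicate block, and the other Gusb probe set were chosen after the results were seen, and the other alternatives were planned. All 12 genes that rose kept a positive change in every one of the 25 alternatives that measured them, and Gpnmb and Cst7, the only 2 of the 13 genes to do so, passed in each that measured them. Of the 23 lists, 12 passed camera in all 25: the 3 lysosomal lists, general and disease-associated microglia, complement, MHC class I, both astrocyte lists, myelin, choroid plexus and meninges. The count of increases was 7 without dim genes, where 6 of the 12 were not tested, 32 with array weights, 5 with 2 regional components, 2 with the replicate block, 6 without mutants 2 and 4, 5 without normals 1 and 3, and 5 to 18 leaving out 1 animal. The count of decreases was 3 with the mean of probe sets, 4 with array weights, 0 with sex and age, with 2 regional components, with the replicate block, without mutants 2 and 4 or without normals 1 and 3, and 0 to 22 leaving out 1 animal. In the alternatives not listed, increases were 8 to 18. Lists past the threshold were 3 with an estimated correlation, 6 with fry, 16 to 28 leaving out 1 animal and 17 to 25 in the others. The interaction gave 0 to 1 genes leaving out 1 animal, and sex gave 1 gene without dim genes. Gusb turned from 0.16 to -0.62 with the mean of probe sets, -0.42 with 2 regional components, -0.12 without normals 1 and 3, -1.40 on the other probe set, and -0.061 to 0.37 leaving out 1 animal, so its sign depends on the probe set and, on 1 probe set, on the animals and covariates. Lists that turned were excitatory synapse (0.0062 without dim genes), thalamus (-0.55 with the first regional component and -0.75 without mutants 2 and 4), neurogenesis (0.015), red cell (-0.19) and striatum (0.064) with 2 regional components, and oxidative phosphorylation (-0.039 without normal 4). Oxidative phosphorylation stayed positive in its other alternatives, at 0.39 without normal 2 and at most 0.52, without normals 1 and 3. Thalamic and striatal genes are among those that define the regional components, so their turns with these covariates were built in. The second component also separated normals from mutants. Calls that ended with 2 components, as for endothelial and cholesterol synthesis genes, may thus have lost part of a genotype difference. The RNA quality difference ran from -0.84 to 0.28 leaving out 1 animal, positive only without normal 1. Apart from fewer genes or animals tested, the cause was not tested. The sign was not compared for genes and lists past the threshold in neither fit. Signal over background limits Cst7 in normals, at 3.23 beside absent controls of up to 3.62.

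Normal and mutant animals share replicate numbers, each number holding 2 animals of 1 sex. Those of numbers 1 and 2 were also of 1 age (38.3 and 25.6 weeks) and had adjoining animal numbers, so matching by design stays open, though the labels do not call them pairs. Deviations from the group means of same-numbered animals correlated at -0.236, 0.0631, 0.395 and -0.155 (Pearson r across genes, which are not independent, numbers 1 to 4). Only for number 3 did both animals correlate best with their own number. This check cannot exclude matching, since the differences in regional markers between arrays enter the same deviations. The planned fit, without pairs, was kept as the main one. With the replicate block, 2 genes rose (Gpnmb and Cst7) and 0 fell, and 24 lists passed. Under it cytokines did not pass (0.087), while immediate early genes (-0.21) and neocortex (-0.35) did, and Gusb stayed at 0.16.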

Other observations

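The genes in this part and the hypothalamic list were chosen after their values were seen, and no explanation of them was tested. With array weights, which ranged from 0.391 for normal 1 to 3.41 for mutant 4, 32 genes passed with higher and 4 with lower values in mutants, and the 12 increases of the report were among the former. Of the other increases, 5 are named here as examples, Lgals3, which encodes galectin 3 (2.49), Itgax, an integrin gene (1.23), Tlr2, a receptor gene for bacterial lipoproteins (0.84), Slc11a1, a phagosomal metal transporter gene (0.96), and Lag3 (1.29).

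Hypothalamic peptide genes were high in 3 arrays of both groups. The mean of the list was 9.56 in normal 2, 9.18 in mutant 1 and 8.12 in mutant 4, against 5.23 to 6.52 in the other 5 arrays (mutant minus normal 0.41, two-sided exact permutation p = 0.8286). Hcrt, which encodes the orexin peptides, was at 10.3, 9.58 and 9.88 in these 3 arrays and 4.51 to 4.80 in the others. Avp, the vasopressin gene, was at 12.3 and 10.3 in the first 2 of them. Neurod6, a transcription factor gene of pyramidal neurons, was at 8.68 in mutant 3 and at 2.75, 2.70 and 2.42 in normal 1, mutant 2 and mutant 4. The values of normal 1, mutant 2 and mutant 4 lay within the range of absent controls (up to 3.62).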
